A study of Mus musculus with 8 samples.

How the data were processed

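RNA of 8 samples, 4 CD44hi and 4 CD44lo subpopulations of Snf5-deficient mouse T cell lymphoma lines, was hybridised to 1-colour arrays. The group and replicate number of each array were taken from its title. The deposited values are probe set intensities that the authors made with Robust Multichip Average (RMA), per the labels' protocols, which corrects background, normalizes between arrays and summarises probes. The version and options of RMA are not given in the sources used here. RMA values are usually on a log2 scale, but the deposited ones lay between 7.61 and 36128 with array medians of 320.3 to 339, so they were read as linear intensity and log2 was taken with no pseudocount. No genome build was used and no coordinates are given. RMA shrinks differences near background, so a fold against a dim group is likely to understate the change; in 42 called genes the lower group's mean lay below the 25th percentile of all values, 5.26.

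Of 22690 probe sets 64 are controls, 20380 carry 1 gene symbol in the platform annotation, 691 several, and 1555 others none there. Symbols were checked through their gene identifier in a mouse RefSeq table (assembly GRCm38.p6), which found 20364 and changed 0. Each of 12393 genes was represented by its probe set with the highest mean over all arrays, and 4956 genes had several. Of 193 called genes with several probe sets, all probe sets had the same sign in 178, and 0 had another probe set called in the opposite direction. Ly6c1, which the naming rule lists, is not analysed here.

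Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate and Benjamini-Hochberg adjustment over all genes. Gene lists, 27 of pathways and 8 of markers of other cell types, were fixed before the data were examined. Of their 671 genes 590 were measured. Lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over 35 lists, with an estimated correlation and fry beside it. The genes named are a fixed set of 10 T cell and design genes where measured, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, passing over clone-named genes, and up to 4 members of each list by smallest p, or 8 for the clearest lists. Cd79a, Cd79b and Gins1 in the results, and the genes the closing section marks, lie outside this rule and were chosen after their values were seen.

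Replicate numbers are shared by the groups, and the labels do not say what they stand for. Deviations of same-numbered arrays from their group means correlated across genes at 0.574, 0.404, 0.533 and 0.531 for numbers 1 to 4. By a rule set before calls were compared (every correlation over 0.1) the numbers were taken to pair the arrays. The pairing thus comes from the values, though arrays of different number correlated nearly as well where both numbers are odd or both even (0.521, 0.471, 0.458 and 0.372), so the values show odd against even numbers more than single pairs. Blocked values stand beside results they change, or in the closing section for members of gene lists. Within groups, arrays 1 and 3 differed by a root mean square of 0.176 (CD44hi) and 0.170 (CD44lo) on the log2 scale, arrays 2 and 4 by 0.297 and 0.192, and arrays 1 and 2 by 0.415 and 0.322.

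The fit was tested on simulated data of 12393 genes with 200 changed. With independent arrays it recovered 41.9%, 85.5% and 97.9% of genes changed by 0.5, 1 and 2 on the log2 scale, with 4.54% of calls false. Arrays were also simulated to differ between odd and even numbers by the same amount in both groups. The fit then recovered 38.4%, 81.3% and 98.2%, with 0.81% of calls false. With the replicate block it recovered 53.6%, 92.4% and 99.2%, with 3.30% of calls false. In the data the group difference itself varied between odd and even numbers for 188 genes (limma interaction, adjusted p under 0.05). The simulated rates do not cover such effects. On independent arrays the block recovered less, 13.6%, 72.4% and 95.5%. In simulations of lists, 1 of 20 runs called an unchanged list and 20 of 20 a list with every member shifted by 0.5. Noise was drawn independently for each gene there, whereas real members can move together (estimated correlation 0.73 for DNA replication genes). These rates therefore do not test the preset correlation. Alternatives were another centring or normalization, filters on dim genes, other choices of probe set, other variance models, array weights, the block, leaving out each array, other thresholds and, added after the data were seen, fits by replicate number.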

Results

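Gene expression was measured on 8 Affymetrix Mouse 430A 2.0 arrays. Per the labels, the RNA came from stable mouse T cell lymphoma lines that lack Snf5 (gene Smarcb1), a core subunit of the SWI/SNF chromatin remodelling complex. Cells had been purified by their surface level of CD44, a hyaluronan receptor that marks memory and activated T cells, into a CD44hi subpopulation (4 arrays) and a CD44lo subpopulation (4 arrays). The median intensity of an array lay between 320.3 and 339 on the linear scale, and the number of arrays limits the precision. The labels do not say that the 4 replicates of a group came from separate cultures or animals, so p-values measure only the spread between these arrays, which may be technical.

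The comparison of CD44hi with CD44lo asks which transcripts differ between the subpopulations of the lymphoma lines. Transcripts of the sorted marker differed in the direction of the labels: Cd44 had a log2 intensity of 11.44 ± 0.28 in CD44hi and 5.55 ± 0.45 in CD44lo (SD, n = 4 each) with the probe set used here, a 59.3-fold difference (log2 difference 5.89, SE 0.23, limma adjusted p = 3.01e-06). The other Cd44 probe set differed by 7.99 on the log2 scale, or 254-fold. Its CD44lo level of 4.19 lay among the CD44lo array medians of bacterial control probe sets (4.12 to 4.38), so that size is uncertain. For each Cd44 probe set, the exact two-sided permutation p was 0.0286, the smallest that 70 assignments allow. Cd44 was the sorting marker, so its difference checks the labels and is no finding about the cells. Both subpopulations carried high Cd8a (13.86 and 13.87), Cd8b1 (13.53 and 13.51) and Cd3e (13.06 and 13.10), which code for the CD8 coreceptor and a T cell receptor subunit, and Cd4 was low in both (5.23 and 5.17). None of these 4 genes passed the test, and nor did Il2rb, an interleukin-2 and interleukin-15 receptor subunit, at 13.11 and 13.27. Smarcb1 was low in both groups, at 6.78 ± 0.10 and 6.85 ± 0.21 (SD, n = 4 each), and did not pass either. Whether its probes lie in the deleted part of the gene is not known here, so its level does not check the labels.

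The largest rise in CD44hi with the probe sets used here was that of Ebf1, a transcription factor of early B cell development, at 11.89 ± 0.44 against 5.30 ± 0.76 (log2 difference 6.58, SE 0.36, limma adjusted p = 1.70e-05). Cplx2, a regulator of vesicle fusion, rose by 6.06 (SE 0.12) from a CD44lo level of 3.98, below the lowest array median of bacterial control probe sets, so the size of this rise is uncertain. Cd86, a costimulatory ligand of antigen-presenting cells, rose by 5.48 (SE 0.35). Adamts1, a secreted metalloproteinase, rose by 4.81. Its CD44lo level of 4.28 lay among the CD44lo array medians of bacterial control probe sets (4.12 to 4.38), so this size is uncertain too. Sowaha rose by 4.53, from a CD44lo level of 4.48 just above those medians, and Art3 by 4.22. Cxcl10, a chemokine ligand of CXCR3, rose by 4.18, from 8.87 ± 0.38 to 13.05 ± 0.15. Ctla2a rose by 4.18, Socs2, an inhibitor of cytokine signalling, by 4.01, Cd24a, a surface glycoprotein of immature lymphocytes, by 3.96, and Neurog2, a neuronal transcription factor, by 3.45. The largest fall with these probe sets was that of Gata3, a transcription factor of T cell development and T helper 2 cells, from 9.78 ± 0.32 in CD44lo to 6.21 ± 0.06 in CD44hi (log2 difference -3.57, SE 0.15, limma adjusted p = 3.05e-06). Slamf6, a lymphocyte receptor of the SLAM family, had a log2 difference of -3.29 and Sln of -3.33. The differences were -2.85 for Nrep, -2.73 for Synpo, -2.49 for Pcp4, -2.34 for Snhg11, -2.34 for the chemokine receptor Ccr2 and -2.14 for Tnp2. Ccr2 was at 4.17 in CD44hi, below the bacterial control median of every CD44hi array (4.19 to 4.37), so the size of its fall is uncertain. The kallikrein proteases Klk4, Klk1b11 and Egfbp2 had differences of -3.30, -2.95 and -2.79, and since close paralogs of this family can hybridise to each other's probes, which of them changed is uncertain. The same holds for Ctla2a and its paralog. Of 24 called genes under the naming rule with several probe sets, 10 had at least 1 that moved under 50% as far as the one used, so their differences depend on the probe set. The weakest differences were 0.04 for Synpo, -0.34 for Sln, -0.13 for Ccr2, 1.10 for Pdgfra, 0.00048 for Id2, 0.01 for Actn1, 0.23 for Il4ra, 0.13 for Bcl2l1, 0.06 for Slc2a3 and -0.24 for Jarid2. The CD44hi level of Slamf6 was set apart by replicate 4, at 9.04 against 8.52 to 8.57.

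**Figure D1:**
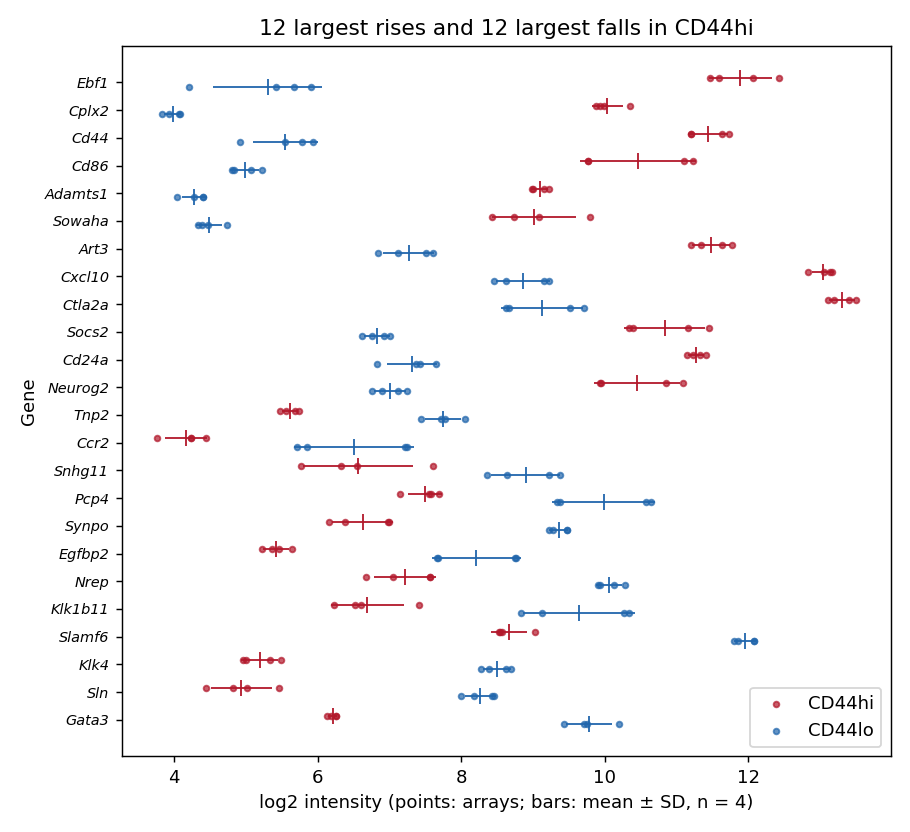
The log2 intensity (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall (vertical axis) in CD44hi, red, and CD44lo, blue. Points are arrays and bars the mean ± SD of 4 arrays. No gene shown has overlapping groups, from Ebf1 with a log2 difference of 6.58 to Gata3 at -3.57.

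Of 12393 genes tested, 252 were higher and 220 lower in CD44hi (limma, Benjamini-Hochberg adjusted p under 0.05), 3.81% of all. At least 2-fold differences were found for 108 of the higher and 68 of the lower genes. In each of the 472 genes the 4 CD44hi values lay on one side of the 4 CD44lo values. Over all genes this held for 1276, or 10.3%. Chance would give 2.86% if all arrays were independent. Arrays numbered 1 and 3, and 2 and 4, resembled each other, so the share that chance gives here is not known. The 10.3% is therefore not shown to be an excess. Arrays with the same replicate number deviated together, and with the replicate number as a block 382 genes were higher and 385 lower, among them 245 and 207 of the genes above. Without CD44lo replicate 2, 3 or 4 the lower genes numbered 128, 142 and 127. If arrays numbered 1 and 3, and likewise 2 and 4, are repeats of one preparation, as their closeness leaves open (less so for CD44hi 2 and 4), each group holds 2 independent values, and limma on their means called 19 higher and 4 lower genes, or 167 and 116 with the pair of numbers as a block. These fits were chosen after the data were seen.

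Of the lists fixed beforehand, naive T cell genes rose (17 measured; median log2 difference 0.18; limma camera adjusted p = 0.0012). The call was lost with an estimated correlation (adjusted p = 0.259). In this list 6 members rose and 0 fell, or 7 and 0 adjusted over the list alone. The lymphoid homing receptors Ccr9 and Ccr7 rose by 2.35 (SE 0.14) and 1.88 (SE 0.17), Nsg2 by 1.82, Pecam1 by 0.99, the interleukin-4 receptor gene Il4ra by 0.77 and Actn1 by 0.66. The other 11 members did not pass. Targets of NF-kappaB, a transcription factor family of inflammation and activation, also rose (17 measured; median 0.21; limma camera adjusted p = 0.0012), a call likewise lost with an estimated correlation (adjusted p = 0.259). Of these, 3 rose over all genes and 7 adjusted over the list alone, with 0 falling. Cd83, an activation marker, rose by 1.59, the NF-kappaB subunit Rel by 0.97 and the kinase Map3k8 by 1.05.

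Of 29 measured memory and effector T cell genes, 5 rose and 2 fell, and the list as a whole did not pass (limma camera adjusted p = 0.398). The survival cytokine receptor Il7r rose by 2.53 (SE 0.20), the chemokine Ccl5 by 2.14 (SE 0.15), Cxcr3 by 0.76, Id2 by 0.54 and Tbx21, the transcription factor T-bet, by 0.33. Ccr2 fell by 2.34 and S100a6 by 0.91. With the replicate block Tbx21 no longer passed (limma adjusted p = 0.0596). Of 20 T cell activation-induced genes, the receptors Tnfrsf4 (OX40) and Tnfrsf18 (GITR) rose by 1.46 and 1.04. Among 16 interleukin-2 and STAT5 targets Socs2 rose by 4.01 and Bcl2l1, which codes for the survival protein Bcl-xL, by 0.70, and Cish fell by 0.55. These 2 lists had limma camera adjusted p of 0.381 and 0.178. By fry, which does not compare a list with other genes, the memory, activation and STAT5 lists passed as higher (adjusted p = 0.0083, 0.0084 and 0.0016).

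Of 17 p53 targets 2 rose and 3 fell (limma camera adjusted p = 0.585). Pmaip1, which codes for the death protein Noxa, rose by 0.84 and Sesn1 by 0.62. The cell cycle inhibitor Cdkn1a fell by 0.93, Btg2 by 0.99 and Phlda3 by 0.75. Of 20 Polycomb and cell cycle inhibitor genes 0 rose and 3 fell, namely Cdkn1a, Jarid2 by 0.63 and Rb1 by 0.44 (limma camera adjusted p = 0.585). The SWI/SNF subunit list had 21 measured genes, of which 0 were called (limma camera adjusted p = 0.940), or Phf10 alone with the replicate block (log2 difference -0.36, limma adjusted p = 0.0368). Of 27 mitotic genes 0 were called, with a median difference of 0.07. Of 29 DNA replication genes 0 were called, or Gins1 alone with the replicate block (log2 difference 0.33, limma adjusted p = 0.0403), with a median of -0.17 and a limma camera adjusted p of 0.070. With the replicate block that list passed as lower in CD44hi (adjusted p = 0.0022), and with the block and an estimated correlation it did not (adjusted p = 0.878). Its median was 0.008 between arrays numbered 1 and 3 and -0.32 between those numbered 2 and 4.

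**Figure D2:**
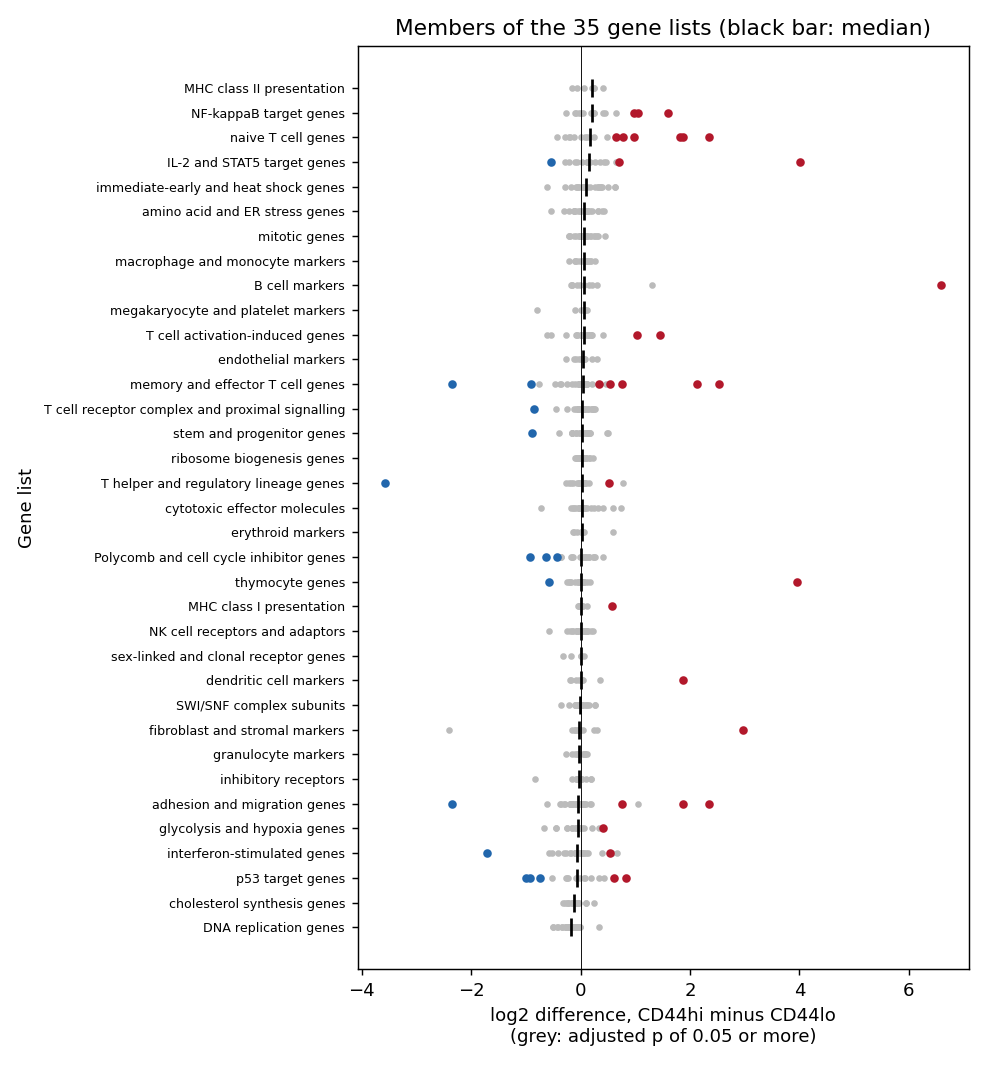
The log2 difference of CD44hi minus CD44lo (horizontal axis) of the measured members of 35 gene lists (vertical axis). Red and blue points are members that rose or fell, grey points did not pass the test, and black bars are list medians, which lie between -0.17 (DNA replication genes) and 0.21 (MHC class II presentation, NF-kappaB targets).

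Among markers of other cell types, Ebf1 was the 1 called gene of 11 measured B cell markers. The abundant B cell transcripts Cd79a and Cd79b, named outside the rule, were at 5.32 and 4.96 in CD44hi and 5.49 and 4.75 in CD44lo, and Ms4a1 was at 4.99 and 3.68 without passing the test. Pdgfra, a growth factor receptor of mesenchymal cells, was the 1 called gene of 14 fibroblast and stromal markers and rose by 2.97 (SE 0.17), while Postn was at 8.17 in CD44hi and 10.57 in CD44lo without passing the test (limma adjusted p = 0.0667). With the replicate block Postn passed as lower in CD44hi (limma adjusted p = 0.0017). The log2 ratio of the 3' to the 5' Gapdh control probe sets, a sign of RNA quality, was 0.816 ± 0.052 in CD44hi and 0.696 ± 0.036 in CD44lo (SD, n = 4 each; exact two-sided permutation p = 0.0286). For Actb it was 0.626 ± 0.152 and 0.498 ± 0.105 (n = 4 each, exact two-sided permutation p = 0.229, which ignores the replicate numbers). At each replicate number the Actb ratio was higher in CD44hi: 0.468 against 0.380, 0.795 against 0.610, 0.532 against 0.442 and 0.710 against 0.558. Whether RNA quality adds to the differences between the groups, those of the gene lists included, was not tested.

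**Figure D3:**
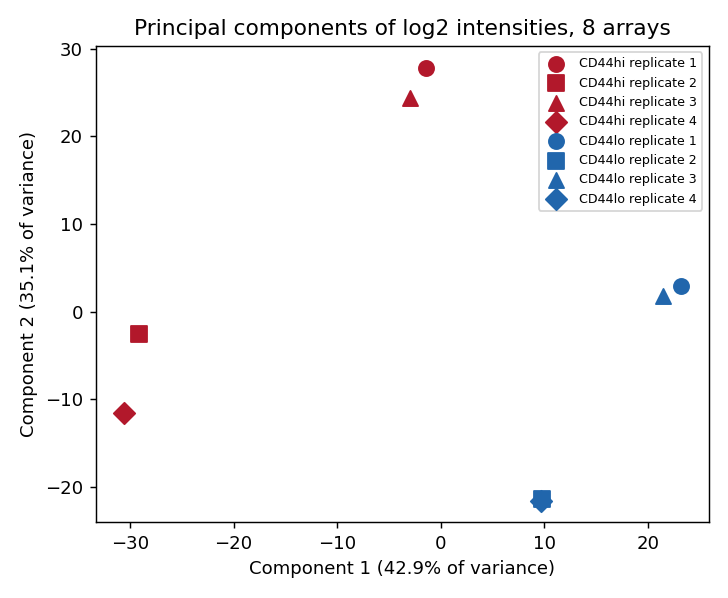
Principal components of the log2 intensities of all genes, component 1 (42.9% of the variance) on the horizontal and component 2 (35.1%) on the vertical axis. Each point is 1 of the 8 arrays, coloured by group and shaped by replicate number. Arrays numbered 1 and 3 lie close together in each group, apart from those numbered 2 and 4.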

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

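The tests of array noise, RNA quality, B cells, stromal cells, dendritic cells and cross-hybridisation were chosen after the results they bear on had been seen.

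In 5 of 134 groups of 4 values examined, 1 array lay far from the others. That is fewer than the 1 in 20 that chance gives for independent, normally distributed values. Most of these genes were picked by small p, and arrays cluster by odd and even number, so the chance rate here is not known. For Slamf6, CD44hi replicate 4 was at 9.04 and the others at 8.52 to 8.57. For Ccr9, CD44lo replicate 1 was at 7.20 and the others at 7.66 to 7.69. For Tap2, CD44hi replicate 3 was at 11.55 and the others at 11.68 to 11.70. For Cd1d1, CD44hi replicate 3 was at 10.46 and the others at 10.21 to 10.25. For Pecam1, CD44lo replicate 4 was at 8.60 and the others at 9.15 to 9.22. Among 2246 probe sets without a single gene name, which only the test of all probe sets uses, 71 differed between the groups (49 higher and 22 lower in CD44hi), or 3.16%, against 3.12% of those with 1 gene.

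Of the 35 splits of the 8 arrays into 4 and 4, 2 called as many genes as the real one (472), so chance is not excluded by this count. The other is the split of numbers 1 and 3 against 2 and 4, which called 2240 genes, the highest of the other splits, and points to a structure of the samples. The 33 remaining splits called 0 genes each. Among the 8 splits that part all same-numbered pairs the highest other count was 0, and these others mix arrays of both groups on each side. With the replicate block the real split called 382 higher and 385 lower genes.

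Arrays numbered 1 and 3 resembled each other, apart from arrays numbered 2 and 4, in both groups. Independent array noise is argued against, since the difference between the numbers correlated across genes between CD44hi and CD44lo (Pearson's r = 0.663; genes are not independent replicates). RNA quality stays open: the 3' to 5' ratio moved with the number for 1 of 2 control transcripts, Actb, and not for Gapdh. Different cell lines also stay open, with 1 gene, Hspa1a, 8-fold apart in the same direction in both groups. The labels name no batch, so preparations, culture states and lines cannot be told apart, and no biological explanation was tested.

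Ebf1, Cd24a, Cd86 and Pdgfra rose in CD44hi, and B cells in the sort as the whole cause are argued against by a median log2 difference of 0.065 over the 11 measured B cell markers, with -0.18 for Cd79a and 0.21 for Cd79b, although Ms4a1 differed by 1.31 (limma adjusted p = 0.0961, or 0.0272 adjusted over the list alone) and fry passed the list as higher (adjusted p = 0.0083). That list holds Ebf1 itself (6.58) and had a mean difference of 0.735. Its fry result is therefore not independent of the rise of Ebf1. Stromal cells are argued against by a median of -0.022 over 14 markers, with 0.05 for Col1a1, and dendritic cells as the whole cause by a median of -0.00044 over 8 markers, although Ccr7 rose by 1.88, Batf3 differed by 0.36 without passing and fry passed the list as higher (adjusted p = 0.0418). Ccr7 was the 1 called dendritic cell marker, and the mean difference of that list was 0.23. Itgax (like Cd79a, Cd79b and Col1a1 outside the naming rule) was at 4.64 and 4.62, and the uncalled class II genes H2-Aa and Cd74 at 5.66 and 5.44 and at 7.10 and 6.68 in CD44hi and CD44lo. The lowest difference among the 10 probe sets of these 4 genes was 1.10, for Pdgfra. Cross-hybridisation of single probe sets is argued against for Ebf1, Cd24a and Cd86, whose lowest probe set differences were 5.19, 3.47 and 4.35. For Pdgfra it stays open, since its probe sets differed by 1.10 and 2.97. Expression by the CD44hi lymphoma cells themselves may account for the rise, a hypothesis found and examined on the same data; these genes are no list fixed beforehand.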

How the results depend on the processing

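Fits by replicate number (1 and 3, 2 and 4, their means, and the block combined with an estimated correlation) were chosen after the data were seen. The Cd44 difference kept direction and call in every alternative (5.53 to 6.94; limma adjusted p up to 0.0206). Of 1448 values of 64 other named genes under alternatives, 1293 kept their side of the threshold, 155 lost the call and 0 called genes reversed; 13 values of uncalled genes changed sign. Against 252 higher and 220 lower genes, the counts were 139 and 144 for genes with a mean above the median (6724 tested), 403 and 418 with array weights, 382 and 385 with the replicate block, 141 and 100 at adjusted p under 0.01, and 108 and 68 with a log2 difference of at least 1. Testing all probe sets called 371 higher and 335 lower probe sets, not genes. Numbers 1 and 3 against 2 and 4 as a block gave 522 and 544, numbers 1 and 3 alone 422 and 450, the averaged arrays 19 and 4, and the averaged arrays with a block 167 and 116. Leaving out 1 array gave 178 to 230 higher and 127 to 226 lower genes; without CD44lo replicate 2, 3 or 4 it was 128, 142 and 127 lower genes.

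Against 2 lists called higher and 0 lower, 4 were higher with a mean above the median, 0 with an estimated inter-gene correlation, 4 with numbers 1 and 3 alone, 5 with numbers 2 and 4 alone, 3 with array weights, 3 without CD44hi replicate 3, and 0 with the replicate block and an estimated correlation. Added were memory and effector and IL-2 and STAT5 genes with a mean above the median (adjusted p = 0.0366 and 0.0219), and ribosome biogenesis genes with array weights (0.0466). Numbers 1 and 3 alone added ribosome biogenesis and ER stress genes. Immediate-early genes were added without CD44hi replicate 3 (0.0163) and, with IL-2 and STAT5 and MHC class II genes, with numbers 2 and 4 alone. For lists called lower there was 1 with centred arrays, 1 with trend and robust variance, 1 with array weights, 1 with the replicate block, 1 with numbers 1 and 3 against 2 and 4 as a block, 1 with numbers 1 and 3 alone, 2 with numbers 2 and 4 alone, 1 with averaged arrays and a block, and 0 to 1 when 1 array was left out. The lower list was that of glycolysis and hypoxia genes with array weights and with numbers 1 and 3 alone, where the median of the DNA replication list turned to 0.01 and 0.008 (adjusted p = 0.975 and 0.833). It was that of DNA replication genes in the other settings, joined by cholesterol synthesis genes with numbers 2 and 4 alone. DNA replication genes passed without CD44hi replicate 1 or 3 (adjusted p = 0.000493 and 0.000239) and without CD44lo replicate 2 or 4 (adjusted p = 0.0104 and 0.0089). Stricter thresholds and filters test or pass fewer genes by construction; for the others the cause was not tested. Of the 163 genes the naming rule gives, the replicate block ended 1 call (Tbx21) and added 8, Postn among them.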

Other observations

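The genes in this paragraph were chosen after their values were seen. Wnt10a and Wnt10b, which code for secreted Wnt ligands, were higher in CD44hi by 2.08 (SE 0.18) and 1.84 (SE 0.13) on the log2 scale, with limma adjusted p of 0.000228 and 7.07e-05. Hoxd9 and Hoxd10, homeobox genes of body patterning, were higher by 1.01 and 1.04. Lgals9, a galectin, was higher by 2.19, from 6.17 ± 0.21 to 8.36 ± 0.07 (SD, n = 4). Beside Slamf6, the SLAM receptors Cd84 and Slamf7 fell by 1.71 and 1.28, and Casp4, an inflammatory caspase, fell by 1.39. All 412 symbol stems with at least 5 measured genes were tested for their share of called genes against other genes (Fisher's exact test, two-sided). Calls of either direction counted, so the test does not ask whether relatives moved the same way. After Benjamini-Hochberg adjustment over the stems 1 passed, Klk, with 6 of 15 genes lower and 0 higher (adjusted p = 0.0045), and paralogs that share probes are not independent. The Wnt stem (2 of 19 higher and 1 lower, adjusted p = 0.994), the Hoxd stem (3 of 7 higher, adjusted p = 0.353) and the Slamf stem (2 of 5 lower, adjusted p = 0.789) did not pass.

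Between arrays numbered 1 and 3 and arrays numbered 2 and 4, Hspa1a, a heat shock gene, had a log2 difference (1 and 3 minus 2 and 4) of -4.19 in CD44hi and -3.60 in CD44lo. For Adm, a hypoxia-induced peptide gene, it was -2.23 and -2.19. Hspa1a and Adm lie outside the naming rule and were chosen after their values were seen. The mitotic list had a median of 0.41 and 0.43 above the member means in CD44hi replicates 1 and 3, and of -0.37 and -0.43 in replicates 2 and 4, with 0.38, 0.43, -0.44 and -0.49 in CD44lo replicates 1, 3, 2 and 4. The group difference itself differed between the pairs of numbers (limma interaction, adjusted p under 0.05) for 188 genes, 34 of them among the 472 called.

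The remaining lists had these results. In interferon-stimulated genes Irgm1 rose by 0.53 and Oas3 fell by 1.72 (limma camera adjusted p = 0.724). In adhesion and migration genes 3 rose and 1 fell (0.940). In T cell receptor genes Vav1 fell by 0.85, in stem and progenitor genes Abcb1b fell by 0.89, in T helper genes Nrp1 rose by 0.52 beside the fall of Gata3, and in thymocyte genes Cd1d1 fell by 0.58 beside the rise of Cd24a. Tap2 rose by 0.58 in MHC class I presentation, Slc2a3 by 0.42 in glycolysis and hypoxia genes, and Ccr7 was the called dendritic cell marker. The lists of cholesterol synthesis, ribosome biogenesis, immediate-early and heat shock, amino acid and ER stress, cytotoxic effector, NK receptor, inhibitory receptor, MHC class II, and sex-linked and clonal receptor genes, and of macrophage, granulocyte, erythroid, megakaryocyte and endothelial markers had 0 called genes (limma), and none passed as a list. With the replicate block some of these and other lists gained members (limma): Ifng (0.59, adjusted p = 0.0179), Hspb1 (0.64, adjusted p = 0.0311), Sesn2 and Chac1 (0.43 and 0.40, adjusted p = 0.0355 and 0.0188), Hk2 (-0.45, adjusted p = 0.0182), Lta and Pim2 (0.64 and 0.47, adjusted p = 0.0220 and 0.0157), Relb (0.45, adjusted p = 0.0497), Cxcr4 (1.05, adjusted p = 0.0258), Oasl2 and Rsad2 (0.57 and -0.41, adjusted p = 0.0399 and 0.0359) and Il18r1 (-0.76, adjusted p = 0.0238). Of these, Chac1, Pim2, Relb, Cxcr4, Rsad2 and Il18r1 lie outside the naming rule. Over all genes 1563 had an unadjusted p under 0.05. By fry, which tests whether a list's genes move one way on balance, 8 lists passed as higher after adjustment: naive T cell, NF-kappaB, IL-2 and STAT5, memory and effector, activation-induced and MHC class I genes, and B cell and dendritic cell markers (adjusted p up to 0.0418). The B cell, dendritic cell and MHC class I lists had 1 called member each, Ebf1, Ccr7 and Tap2, and the MHC class I median difference was 0.0017. In all 8 lists the mean difference was above the median, as in IL-2 and STAT5 genes (0.38 and 0.15, with Socs2 at 4.01). Passing by fry is thus no sign that most members moved.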
